A study of Glycine soja with 2 samples.

How the data were processed

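The data are Visium spatial expression libraries from 2 sections of wild soybean (Glycine soja) seed, titled ZYD_H and ZYD_V. Visium captures polyA RNA from a tissue section on a slide printed with barcoded spots. A spot can cover several cells, and each captured molecule carries a unique molecular identifier (UMI). Per the labels' protocols, the tissue was fresh frozen and cut at 10 µm. The labels give 1 library per title and do not say what H and V stand for. Spot positions and tissue images were not used here, so regions below are groups of spots with like expression, without a place in the seed.

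For each section the authors deposited a matrix of counts, whole-number UMIs per gene and spot, with a list of genes and a list of spots. Per the submitters' processing notes, Space Ranger made the counts. Per the file headers, its version was 2.0.1 for ZYD_H and 1.2.0 for ZYD_V, so software version and section cannot be told apart. The aligner settings, genome build and annotation are not given in the sources used here. Both matrices list the same 55539 genes in the same order. The files hold gene IDs without names. The RefSeq table of Glycine soja used for names (assembly ASM419377v2) has 59365 genes, and 0 of the 55539 IDs matched it. The 22 gene lists fixed before the data were examined, defined by product descriptions, therefore held no genes and gave no result. The comparisons planned on them, between sections, across regions and across spots, were not made.

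Spots with under 500 UMIs were left out, which removed 0 of 1219 spots of ZYD_H and 1 of 1961 spots of ZYD_V. Counts were summed over the spots of each section and scaled to CPM (counts per 1000000 UMIs). The log2 ratio of ZYD_V over ZYD_H was given for genes with at least 100 UMIs over both sections, with an exact conditional binomial 95% interval. A gene was counted as apart where the whole interval lay beyond 2-fold. With 1 library per title there is no test between sections and no p-value. All intervals cover counting error only, not the spread between seeds, sections or libraries. Shares have exact (Clopper-Pearson) intervals. A fold against a count of 0 is a lower bound, computed against a floor of 3 counts in that section, which is less strict than the lower end of the 2-sided 95% interval. TMM factors came from edgeR 4.0.16 and size factors from DESeq2 1.42.0 in R 4.3.3. Both were used for scaling only.

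Regions were made from the spots of both sections together. Counts were scaled to 10000 per spot and logged, and 2000 variable genes were centred and scaled within each section. The first 20 principal components gave a graph of 15 neighbours, which was divided by Leiden clustering at resolution 0.5 with seed 0. Regions were numbered by size. Contrasts of a region against the other spots of its section used genes outside the clustering set and a pseudocount of 1 CPM. To compare genes per spot at a fixed depth, each spot was thinned at random to 5000 UMIs and shallower spots were left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and python-igraph 0.11.9 were used.

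The plan fixed before the data were examined did not say how variable genes are ranked or how distance is measured. In all, 5 versions of these choices were tried on simulated spots and 2 of them on the real spots. The first ranked genes by dispersion. Its result on the real spots had been seen before it was replaced by the version used here, which ranks genes by the variance of Pearson residuals (overdispersion 0.01) and takes the larger rank of the 2 sections. The change followed tests on 1000 simulated spots drawn with 3 profiles shared by both sections, and it was not better in every case. With weak profiles at full depth the adjusted Rand index was 1.0 for the dispersion ranking and 0.606 for the residual ranking. With the same spots thinned it was 0.0 and 1.0. With strong profiles both rankings split each profile by section at full depth, with 0 regions shared, and after thinning the index was 0.0 and 0.903. Both found 1 region in spots simulated without structure. Cosine distance was dropped because it found 3 or 4 regions there. Results of both rankings on the real spots are given.

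The section comparison was tested on simulated counts. Of changed genes, 93.6% were recovered at 3-fold and 99.0% at 4-fold, and 0 of 27387 unchanged genes were called. Both simulated libraries came from the same profile with counting error only, apart from the changed genes. These rates therefore do not bear on the spread between libraries or on the choice of scaling.

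Genes to be named were fixed by rule before the data were examined. Genes without a product name are given by ID only, at most 2 higher and 2 lower, ordered by the interval bound nearest 0. The 10 genes with most UMIs are summarised without IDs for the same reason. Alternatives fixed beforehand covered scaling, the UMI minimums, equal weight per spot or region, the resolution, the number of genes and components, and clustering of each section on its own. Thinning, the dispersion ranking, 3 and 5 components, resolutions under 0.3, leaving out abundant genes, scaling to the median gene, and all analyses of expression axes were chosen after seeing the data.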

Results

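Spatial expression was measured in 2 sections of developing wild soybean seed, ZYD_H and ZYD_V, with 1 library each. The ZYD_H matrix held 1219 spots and 23702069 UMIs. The ZYD_V matrix held 1961 spots, of which 1960 were kept with 97417495 UMIs. The median spot had 12307 UMIs and 3667 genes in ZYD_H, and 51502 UMIs and 7259 genes in ZYD_V, a 4.18-fold difference in depth and a 1.98-fold difference in genes. At least 1 UMI was found for 38225 genes in ZYD_H and 36890 genes in ZYD_V. There was no replicate of either section, so each difference below is between these 2 libraries and carries counting error only.

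With every spot thinned to 5000 UMIs, the order of the sections in genes per spot turned. The median was 1950 genes in 1211 spots of ZYD_H and 1673 genes in 1854 spots of ZYD_V, with 8 and 106 shallower spots left out. Within ZYD_H the deepest 25% of the spots had a median of 2870 genes at this fixed depth and the shallowest 25% had 1715. Within ZYD_V the medians were 1807 in the deepest 25% and 2022.5 in the shallowest 25%.

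**Figure D1:**
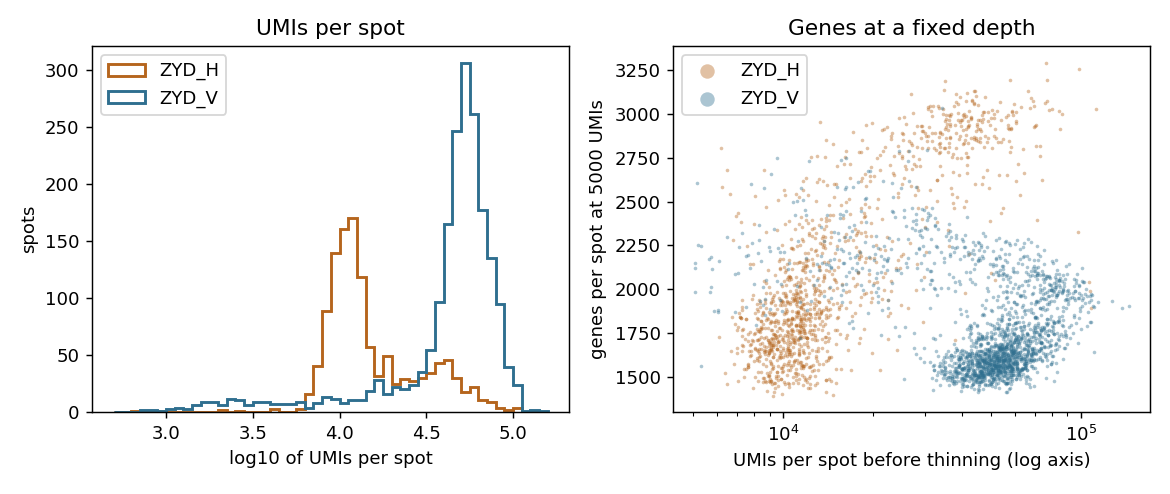
Left, number of spots by log10 of UMIs per spot in each section; right, genes per spot after thinning to 5000 UMIs against UMIs per spot before thinning (log axis), 1 point per spot. The median spot has 12307 UMIs in ZYD_H and 51502 in ZYD_V, and at 5000 UMIs the medians are 1950 and 1673 genes.

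Transcripts were concentrated in fewer genes in ZYD_V. The 10 most abundant genes of each section took 18.2% of UMIs in ZYD_H and 20.7% in ZYD_V, with 2 genes in both sets. The 100 most abundant genes of each section took 35.7% of UMIs in ZYD_H (95% exact interval 35.67 to 35.71) and 51.3% in ZYD_V (51.31 to 51.33), and 37 genes were in both sets. The 1000 most abundant took 58.5% and 74.97%, with 501 in both. Of the 10 genes with most UMIs over both sections, 7 were at least 2-fold higher in ZYD_V by CPM, 1 was at least 2-fold lower and 2 were within 2-fold. With TMM factors or size factors 8 were higher, 0 lower and 2 within 2-fold. This set was ranked on pooled UMIs, of which ZYD_V held 4.11 times as many, so it favours genes that are high in ZYD_V. A level of 1000 CPM or more was reached by 72 genes in ZYD_H, of which 3 were under 10 CPM in ZYD_V. It was reached by 119 genes in ZYD_V, of which 11 were under 10 CPM in ZYD_H.

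The section titles imply a comparison of ZYD_V with ZYD_H over the whole section. Of 25642 genes with at least 100 UMIs, 2475 lay beyond 2-fold higher in ZYD_V with their whole counting interval and 11518 beyond 2-fold lower. CPM levels correlated with r = 0.56 on the log2 scale and rho = 0.51 across genes, which are not independent replicates. The median gene had a log2 ratio of -1.02, and the middle 50% of the genes lay between -2.45 and 0.06. The split of higher against lower depended on the scaling. It was 7222 against 5898 with TMM factors and 7598 against 5687 with size factors, where the median log2 ratio was 0.30 and 0.37. Relative to the median gene, a scaling chosen after seeing the data, it was 5677 against 6889. The direction of the median gene thus turned with the scaling. With a minimum of 500 UMIs and scaling by total UMIs, the split was 1993 against 5528 of 15908 genes, with a median log2 ratio of -0.59.

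The largest ratios were far beyond these shifts. Glysoja.20G052802 had 0 UMIs in ZYD_H and 174463 in ZYD_V, where 1928 spots held it, and was at least 14149-fold higher by CPM against a floor of 3 counts. The 95% interval of its log2 ratio began at 13.49. Glysoja.01G002276 had 0 UMIs in ZYD_H and 116699 in ZYD_V, at least 9464-fold higher against that floor, with an interval from 12.91. Glysoja.14G037572 had 6789 UMIs in 768 spots of ZYD_H and 3 UMIs in ZYD_V, a log2 ratio of -13.18 (95% interval -15.46 to -11.64). Glysoja.16G042788 had 2725 UMIs in 513 spots of ZYD_H and 0 in ZYD_V, and was at least 3733-fold lower there against that floor, with an interval up to -11.57. For the 3 genes with a count of 0, a low level cannot be told apart here from a gene model left uncounted in that section, in which case the bound would not hold. The names and functions of these 4 genes are not given in the sources used here.

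**Figure D2:**
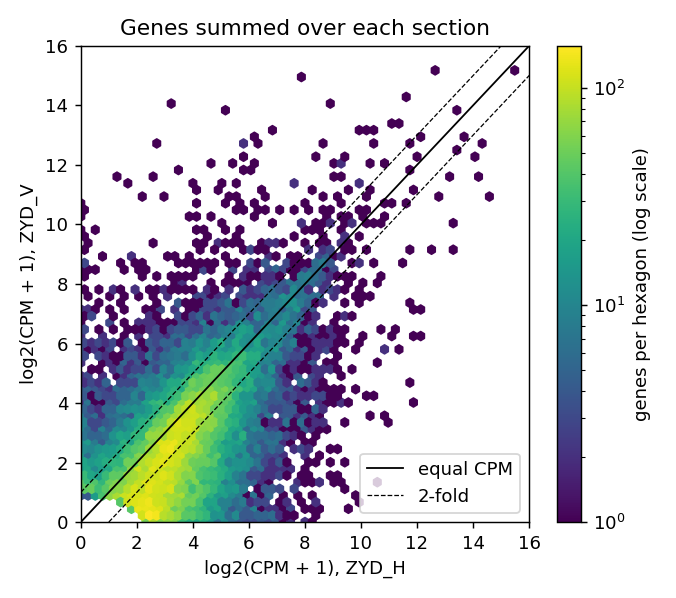
Genes with at least 100 UMIs over both sections by log2(CPM + 1) in ZYD_H and ZYD_V, coloured by the number of genes per hexagon on a log scale; the solid line marks equal CPM and dashed lines 2-fold. Most of the 25642 genes lie below the solid line, with a median log2 ratio of -1.02.

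Clustering of the spots of both sections together gave 18 regions, and none held at least 20 spots of each section. At least 96.1% of the spots of each region came from 1 section. ZYD_H spots filled 6 regions of at least 20 spots, with 25 to 307 spots each. ZYD_V spots filled 11, with 42 to 407 spots. The largest regions of ZYD_H were region 3 with 25.2% of its spots (95% exact interval 22.8 to 27.7) and region 4 with 24.8% (22.4 to 27.3). The largest of ZYD_V were region 1 with 20.8% (19.0 to 22.6) and region 2 with 16.7% (15.1 to 18.4). Median depth ranged from 9901 to 35108 UMIs over the regions of ZYD_H and from 3197 to 74606 over those of ZYD_V. At 5000 UMIs, region 13 of ZYD_H had the most genes per spot among these, 2890, and region 1 of ZYD_V the fewest, 1518.

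This separation of the sections depended on the number of components, the depth and the gene ranking. Over 2 gene rankings, full and thinned depth, 3 numbers of components and 6 resolutions, 54 of 72 settings gave at least 1 region with 20 spots of each section, and up to 8. At 20 components and full depth both rankings gave 0 at each of the 6 resolutions. With thinned spots and 20 components the residual ranking gave 0 at each, and the dispersion ranking gave 1 or 2 at each. On thinned simulated spots the dispersion ranking merged 3 shared profiles into 1 region, so shared regions there can come from unresolved profiles. With 5 or 3 components each setting gave at least 1. With 3 components at resolution 0.5 and the residual ranking, 6 shared regions held 50.5% of ZYD_H spots and 32.7% of ZYD_V spots. The settings with 3 and 5 components were chosen after seeing the data. The count of 0 at 20 components and full depth does not show that the sections share no tissue, since the same clustering also split simulated profiles that both sections shared.

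**Figure D3:**
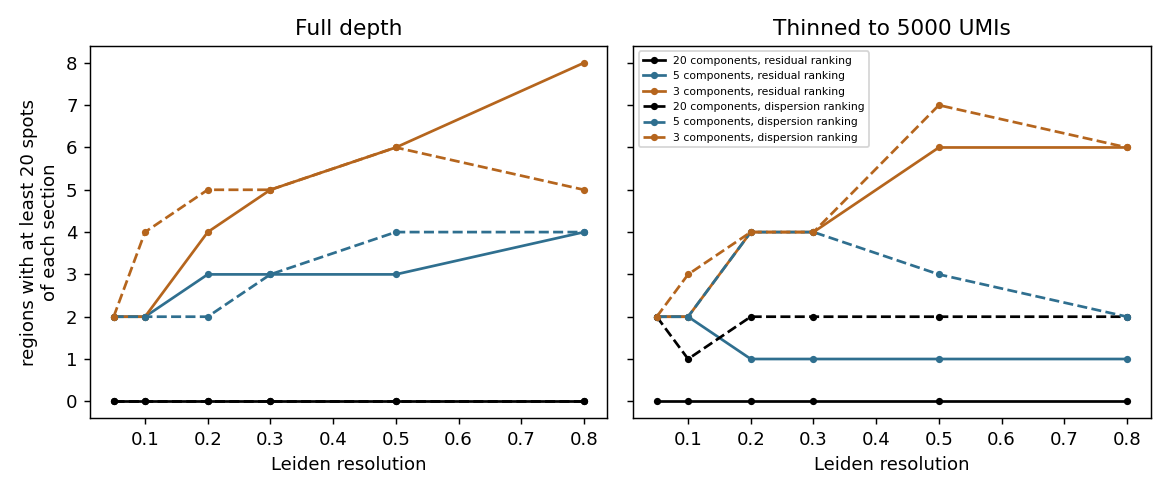
Regions with at least 20 spots of each section against Leiden resolution, at full depth (left) and with spots thinned to 5000 UMIs (right), for 20, 5 and 3 components (colours) and the residual (solid) and dispersion (dashed) gene rankings. At full depth both rankings with 20 components stay at 0, and 3 components reach up to 8.

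Regions of the 2 sections were also compared by their contrasts against the other spots of the same section, over 15377 genes outside the clustering set. Of 66 pairs of a ZYD_H region with a ZYD_V region, 8 had r of at least 0.3 across genes, and the median was 0.08. The highest was 0.52 for regions 6 and 11, and the lowest was -0.54 for regions 3 and 11. Region 6 was among the deeper regions of ZYD_H with a median of 33520 UMIs, while region 11 was the shallowest of ZYD_V with 3197. Within a section, pairs of regions had r between -0.86 and 0.80. Regions of 1 section are part of each other's contrasts, so these values cannot be set against those between sections.

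**Figure D4:**
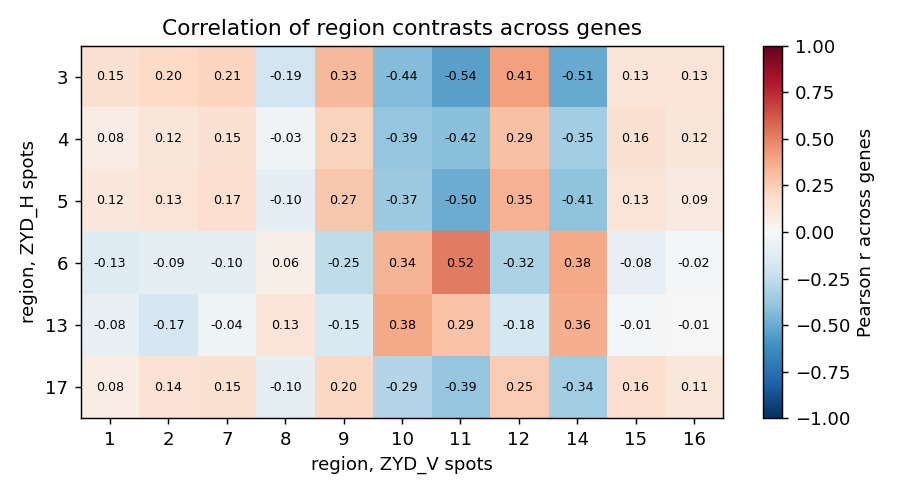
Pearson r across 15377 genes between the contrast of each ZYD_H region (rows) and each ZYD_V region (columns) against the other spots of its own section. The highest value is 0.52 for regions 6 and 11 and the lowest -0.54 for regions 3 and 11.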

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

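The tests in this part, and the results other than the count of shared regions, were chosen after seeing the data. For that count the number of components and the resolution were fixed beforehand, but the gene ranking was not.

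Genes per spot at 5000 UMIs had log2 ratios of opposite sign between the deepest 25% and the shallowest 25% of the spots, 0.74 in ZYD_H and -0.16 in ZYD_V. Across the spots that reached the fixed depth there was little trend in ZYD_V, with rho = -0.090 at 2000 UMIs, -0.024 at 5000 and 0.032 at 10000, against 0.70, 0.72 and 0.76 in ZYD_H. The spots left out as too shallow numbered 40, 106 and 159 of 1960 in ZYD_V and 2, 8 and 297 of 1219 in ZYD_H. At 2000 UMIs the log2 ratios were 0.73 in ZYD_H and -0.21 in ZYD_V. The difference between the sections was not tested. The expression axes that the sections shared were turned so that scores rose with UMIs per spot in ZYD_H. Those of ZYD_V were turned to the same genes. The positive direction in ZYD_H is therefore a choice, and only that in ZYD_V relative to it was observed. UMIs per spot differed in direction along the first shared axis, with a log2 ratio of upper over lower end of 1.78 in ZYD_H and -1.69 in ZYD_V. Along the second shared axis these ratios were 1.45 and -0.0031, the latter close to 0. Neither difference was tested.

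No region held at least 20 spots of both sections at 20 components and full depth. A difference in depth may contribute. With every spot thinned to 5000 UMIs the count was 2 under the dispersion ranking and 0 under the residual ranking. On thinned simulated spots the dispersion ranking merged the 3 shared profiles into 1 region, so its count of 2 can come from unresolved profiles. There the residual ranking gave 3 shared regions with weak profiles and 2 with strong ones. The difference in depth between the sections remains neither shown nor excluded as a cause. Leaving out a few abundant genes, the 100 with most UMIs of each section, left the count at 0, but this excludes nothing, since the same clustering gave 0 shared regions for strong simulated profiles that both sections had. Different processing software versions cannot be told apart from the section, because 0 sections were processed with both. With 3 components the same spots gave 6 shared regions, so the pattern is in part a matter of how many components are used. The difference between the seeds or stages that the titles may stand for was not tested.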

How the results depend on the processing

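The alternatives for axes, for genes at a fixed depth, for the dispersion ranking, 3 or 5 components, thinning, resolutions under 0.3 and the median gene were chosen after seeing the data. The causes of the changes below were not tested. Genes beyond 2-fold numbered 7222 higher and 5898 lower in ZYD_V with TMM factors, 7598 and 5687 with size factors, and 5677 and 6889 relative to the median gene. With a minimum of 500 UMIs, where fewer genes were counted, 5528 were lower. The other settings fixed beforehand kept both counts within 1.5 times. Clustering on all genes equals the main setting, because the fixed lists were empty, and the alternatives meant for the lists were not run for that reason.

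Regions holding 20 spots of each section stayed at 0 in the 6 alternatives fixed beforehand that give this count. With the residual ranking they numbered 3 (5 components) and 6 (3 components) at full depth, and 1 and 6 with thinned spots. With the dispersion ranking they numbered 4 and 6 at full depth, 3 and 7 with thinned spots, and 2 with 20 components and thinned spots. The number of regions was 5 at resolution 0.05, 6 at 0.1, 9 at 0.2, and 11 with the dispersion ranking, 20 components and thinned spots. Clustered on its own, ZYD_H gave 11 regions of at least 20 spots.

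The first axis correlation of 0.78 was 0.75 with thinned spots, 0.82 with 1000 genes, 0.74 with 3000, and 0.77 without the shallowest 10% of the spots. Without the shallowest 25% it was 0.14 for the same axis numbers and 0.60 for the best-matching axis. The second, 0.74 in the main setting, was 0.71 without the 100 most abundant genes, 0.81 without the shallowest 10% and 0.46 without the shallowest 25%, where the best-matching axis was the same one. Genes higher at the upper end of the first axis in both sections, lower in both, and opposite numbered 184, 3 and 24 with at least 500 UMIs per section (against 118.9, 6.34 and 111.6 for independent lists), and 1016, 23 and 78 without the shallowest 25% on the best-matching axis. Relative to the median gene 988 were higher and 420 lower, and with 10% of the spots at each end 266 were opposite. The log2 ratio of ZYD_H over ZYD_V in genes per spot at a fixed depth was 0.16 at 2000 UMIs, 0.22 at 5000 and 0.39 at 10000. The last is over other spots, since 297 of 1219 ZYD_H spots were left out as too shallow at 10000 UMIs, against 8 at 5000 and 2 at 2000.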

Other observations

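The analyses in this part were chosen after seeing the data. Of the tests, those of spot depth, shallow spots, uncounted gene models and neighbouring gene models were set after the values they bear on had been seen, and the shuffles by mean level before.

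The sections shared no region of at least 20 spots of each at 20 components and full depth, but the gene loadings of the leading axis of expression across spots were correlated between them. Principal components were computed in each section on its own over the same 2000 genes, chosen for ranking high in variance in both sections. The first axis took 23.4% of the variance in ZYD_H and 20.2% in ZYD_V, and the loadings correlated with a size of 0.78 across these genes. The correlation therefore does not cover genes variable in only 1 section. It was 0.82 with 1000 genes chosen in this way and 0.74 with 3000. The second axis of ZYD_H matched the third of ZYD_V with 0.74, less stably, with 0.64 to 0.76 over 20 random draws of 50% of the spots and 0.46 without the shallowest 25%. The folds between the ends of this second pair had rho = 0.19 over genes outside the clustering set, against 0.51 for the first. The second axis of ZYD_V, with 12.02% of its variance, matched no axis of ZYD_H among the 4 examined, with a largest size of 0.22. Over the same draws the first correlation lay between 0.77 and 0.79. The spots along the first axis differed between the sections. Its score followed genes per spot at 5000 UMIs with rho = 0.93 in ZYD_H, where the ends had medians of 2874 and 1635.5 genes, and with -0.12 in ZYD_V, with 2056 and 1935.5. These values leave out spots under 5000 UMIs, 8 in ZYD_H and 106 in ZYD_V. In region 11, the ZYD_V region with the highest median of genes per spot, 43 of 143 spots were kept. Genes outside the clustering set needed 100 UMIs over the 2 ends in each section. They were counted by the ratio alone, a looser rule than the whole interval used between the sections. Of 12385 such genes, 1637 were at least 2-fold higher at the upper end of the first axis in both sections. That compares with 1050 if the 2 lists were independent. A further 66 were lower in both, against 25.1, and 137 were opposite, against 478.3. In ZYD_H alone 6912 of these genes were higher at the upper end and 419 lower, with a median log2 ratio of 1.14. In ZYD_V alone 1882 were higher and 743 lower, with a median of 0.05. That more genes were higher than lower in both depends in part on this shift in ZYD_H. The counts of genes higher in both, lower in both or opposite moved with the settings. With at least 500 UMIs per section 184 were higher in both, against 118.9, but 3 were lower in both, against 6.34, so the excess of lower genes was not seen there. Relative to the median gene 988 were higher in both, against 340, and 420 lower, against 135.9. Without the shallowest 25% of the spots, on the best-matching axis, 1016 were higher, against 874, 23 lower, against 4.05, and 78 opposite, against 119.2. With 10% of the spots at each end 266 were opposite, against 696. The same spots define the axis and give these folds, so they describe these sections only.

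Several causes of this shared axis were weighed. The number of UMIs sampled per spot is argued against as a common cause. The correlation was 0.75 with spots thinned to 5000 UMIs and shallower spots left out. The upper end, which was set to be the deeper end in ZYD_H, also held the shallower spots in ZYD_V. The score followed UMIs per spot with rho = 0.66 in ZYD_H and -0.59 in ZYD_V. Expression that goes with depth is not removed by thinning, so it is not excluded. The mean level of the genes gave at most 0.35 in 1000 shuffles among genes of like level. Shallow spots of either section stay open in part. Without the shallowest 25% the correlation was 0.14 for the same axis numbers. The first axis of ZYD_H then matched the second of ZYD_V best, with 0.60. A tissue gradient present in both sections may underlie the axis. Its relation to genes per spot was not alike in the sections among spots of at least 5000 UMIs. That comparison lacks most spots of region 11 of ZYD_V, so it does not decide the question. To examine this, spot positions and gene names would be needed.

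Some genes had 0 UMIs in 1 section where the other section's level, scaled by total UMIs, predicted 1000 or more. The numbers below depend on that scaling. There were 17 in ZYD_H among 2316 such genes and 30 in ZYD_V among 12571. For gene models left uncounted in 1 section, genes at 0 were compared with genes at low counts. The bar set in favour of this cause, 2 genes at 0 per gene with 1 to 5 UMIs, was not reached, with 17 against 19 in ZYD_H and 30 against 91 in ZYD_V. The bound for excluding it was first set at no more genes at 0 than with 1 to 5 UMIs, which these counts meet. It was replaced after they were seen, because that range spans 5 values, by a comparison with genes at exactly 1 UMI. Over both sections there were 1.24 genes at 0 per gene with exactly 1 UMI, with 17 against 6 in ZYD_H and 30 against 32 in ZYD_V. Neither comparison is a requirement of the cause, since uncounted models set no number of other genes at low counts. Uncounted gene models therefore stay open in both sections. Reads assigned to a neighbouring gene model instead are argued against for the 47 genes as a set, but not for each gene. The 2 features on either side held an excess of at least 50% of the missing count for 2 of the 47 genes, under the median of 6 in 1000 random sets. For those 2 genes this cause stays open.

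Ratios between the sections were weakly alike for neighbouring genes. The log2 ratio of ZYD_V over ZYD_H correlated with r = 0.09 over 13533 pairs of consecutive genes in the list, beyond the 0.026 reached in 1000 shuffles, but at 2 places apart r was 0.02602, not beyond the largest shuffled value of 0.02618, and at 500 places apart it was 0.021.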
